A study of Homo sapiens with 2 samples.

How the data were processed

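Total RNA of Ca9-22 cells stably transduced with an empty vector or a RUNX2 vector and selected with blasticidin was extracted with silica columns, and biotin-labelled cRNA was hybridised to Affymetrix human arrays, 1 per group, per the labels' protocols. The authors deposited 1 intensity per probe set and array on a linear scale, for 54675 probe sets. The submitters' processing notes name MAS5, without a version or a scaling target. The deposited intensities ran from 3.92 to 25079 on the empty vector array and from 4.14 to 25253 on the array labelled RUNX2. Their 2% trimmed means differed (199 and 206), 1448 probe sets had values on both arrays that were equal in every deposited digit, and log2 ratios spread less among the lowest levels (SD 0.206 in the lowest of 12 level classes) than higher up (0.473 in the widest class). Plain MAS5 signals usually spread most at low levels, so how the intensities were summarised and scaled is left open, and levels are in arbitrary units. Detection calls and scanner files were not used here. Samples were grouped by their titles, and both sample columns entered the comparison.

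The choices below, the gene lists, the rule for named genes and all alternatives except those named as added were fixed before the data were examined. The 62 control probe sets were left out. The array labelled RUNX2 was multiplied by 0.966 to equal the 2% trimmed means. The floor was the median of each array, 55.3 for the empty vector array and 51.8 for the scaled array labelled RUNX2. A probe set was measured if it exceeded the floor on at least 1 array. A value below the floor was raised to it, and the ratio is then a bound, written "at least". Log2 ratios are array labelled RUNX2 over empty vector.

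Genes were named from the platform's annotation, where 41091 probe sets had 1 symbol, 1801 had several and 11721 were not named. The symbols of 41043 were looked up by Entrez ID in a RefSeq gene table of assembly GRCh38.p14, from which no coordinates are given, since the sources used here name no build. Probe sets with several symbols named no gene. The measured probe set with the highest mean log2 level stood for its gene. The spread of log2 ratios between probe sets of 1 gene had an SD of 0.293 over 6165 genes with 2 or more measured probe sets, which is a technical spread within arrays and no replicate error. The median log2 ratio over all 12729 genes was -0.06.

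With 1 array per group, no test between groups was made. Genes were counted at a threshold of 2-fold. For 30 gene lists fixed in advance, the median log2 ratio of the measured members was ranked among 10000 random lists of the same size drawn from the other measured genes and matched on mean level in 20 bins. A list with fewer than 5 measured members was not ranked. A list was said to lie above or below the limits at or beyond percentile 97.5 or 2.5, as a description of these arrays. The lists covered the RUNX family, osteoblast genes, proteases, activin, TGF-beta and BMP signalling, EMT, epithelial junctions, basal keratinocytes, keratinocyte differentiation, G1/S and replication, mitosis, p53 targets, interferon-stimulated genes, MHC, cytokines, hypoxia and glycolysis, growth factors, immediate early genes, the unfolded protein response, NRF2, lipid synthesis, heat shock, integrins and matrix, Wnt and Notch, ribosomal proteins, oxidative phosphorylation, reference genes, and markers of fibroblasts, leukocytes, endothelium and simple epithelium. Some genes stand in more than 1 list.

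Named genes were 12 chosen in advance, of which 10 had a probe set of their own and are given, the 10 highest and 10 lowest ratios among genes whose other measured probe sets did not go the other way, the next 6 in each direction with at least 2 measured probe sets all at least 1.5-fold the same way, and up to 4 members per list with the widest ratio. The text gives most of these. ISG15, IFIT1, IRF1, IL1B and the genes of added families were named after their values were seen.

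Alternatives were the deposited scale without a factor, equal medians, quantile normalization, loess on level (span 0.4), floors at the 25th and 75th percentile, no floor, an offset equal to the floor, the mean over probe sets, leaving out probe sets whose ID ends in _x_at or _s_at, thresholds of 1.5-fold and 4-fold, and random lists not matched on level. Each RUNX2 probe set by itself, the interferon list without members of the cytokine and MHC lists (none was measured in both), and the G1/S list without its 2-fold higher members were added after seeing the data. The scripts were tested on simulated arrays built from the measured values. Of 200 genes given a 4-fold change, 97.5% were recovered at 2-fold, and 77 unchanged genes passed it among 12682 genes in the simulated test. The simulated spread came from the log2 ratios of this same pair of arrays, so these values are no replicate error rate. Smaller changes of single genes were not simulated, and the simulated lists held genes drawn independently. Of 100 lists of 25 genes with no shift, 6 lay outside the limits, and 99 of 100 lists shifted by 0.3 on the log2 scale lay above the upper limit. Python 3.11.15 was used with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.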

Results

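Gene expression was measured in Ca9-22 cells, a line established from a squamous carcinoma of the gingiva, after stable transduction with an empty vector or with a vector for RUNX2, the runt-domain transcription factor best known as the master regulator of osteoblast differentiation. The comparison asked which transcripts differ between cells of this oral cancer line with the RUNX2 vector and cells with the empty vector. Each group held 1 array, so there are no replicates. No test between the groups and no p-value is given, and the number of arrays limits the precision of every value. Differences were sorted by a fixed rule of size, at least 2-fold, and are described as higher or lower in the array labelled RUNX2 relative to the empty vector array. Of 54613 probe sets that are not controls, 23332 carried 1 gene symbol and exceeded the median of at least 1 array, and these represented 12729 genes. Log2 values of the arrays correlated with r = 0.986 across all probe sets and r = 0.968 across those above the floor on both arrays, where probe sets are not independent replicates.

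The RUNX2 probe sets did not go the same way. Of 6 probe sets for RUNX2, 3 were above the floor. The level of 216994_s_at was 204 on the empty vector array and 854 on the array labelled RUNX2, 4.17-fold higher, and 221282_x_at was 3.47-fold higher, at 102 and 353. In contrast, 232231_at read 1746 on the empty vector array and 433 on the array labelled RUNX2, 4.03-fold lower. As the brightest of them, 232231_at stood for the gene under the rule set for every gene, which gave RUNX2 a log2 ratio of -2.01, and the mean over its probe sets gave 0.62, the opposite sign. The target gene therefore does not settle the labels of the arrays, and each direction given here rests on the labels alone. RUNX3 had a log2 ratio of -0.73, with -0.67 in another probe set and a bound of 0.12 in a further one. CBFB, the partner subunit that does not bind DNA itself, had -0.10, with 0.41 in another probe set. The 10 measured genes of the RUNX family and its cofactors, with RUNX2 counted at -2.01, had a median log2 ratio of -0.15. This was percentile 15.8 of 10000 random lists of the same size matched on level. That rank describes these arrays and is not a test.

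**Figure D1:**
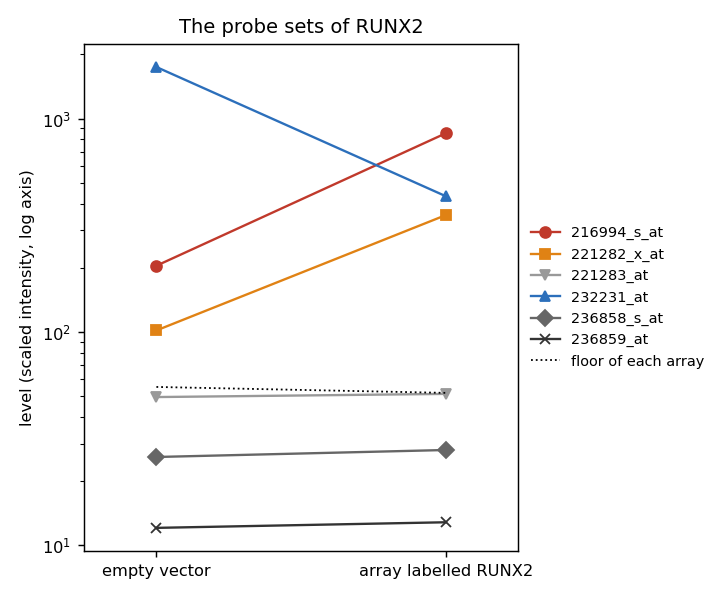
Level of each RUNX2 probe set (scaled intensity, log axis) on the empty vector array and on the array labelled RUNX2, with 1 line per probe set and a dotted line for the floor of each array. The probe sets 216994_s_at and 221282_x_at are higher in the array labelled RUNX2, 232231_at is lower, and the other 3 lie below the floor on both arrays.

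In the array labelled RUNX2, 180 genes were at least 2-fold higher and 187 were at least 2-fold lower. RUNX2 itself is counted among the lower genes, through its brightest probe set. The widest differences upwards were in FGFBP1, a secreted carrier of fibroblast growth factors (10.6-fold, from 168 to 1770), GJB2, a gap junction connexin (9.56-fold, from 101 to 962), the protocadherin PCDH7 (9.43-fold, and 2.59-fold in another probe set above the floor on both arrays), the oxidised lipoprotein receptor OLR1 (7.26-fold, from 238 to 1730) and the interferon-stimulated gene IFI44L (7.22-fold). IL36G, an epithelial cytokine below the floor on the empty vector array, was at least 6.90-fold higher. The neutrophil chemokine CXCL8 was 5.91-fold higher and ERRFI1, a feedback inhibitor of the EGF receptor, was 5.15-fold higher. INHBA, which encodes the activin A subunit, was 4.88-fold higher, from 252 to 1230, with log2 ratios of 2.11 and 2.29 in its 2 measured probe sets. XDH, the enzyme that makes uric acid, was 4.03-fold higher in its brightest probe set and 2.25-fold in the other.

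The widest difference downwards was in the long non-coding RNA LOC101928505 (7.90-fold, from 1783 to 226). TEX19, a gene known from germ cells, was 5.93-fold lower. TXNIP, which binds and inhibits thioredoxin, was 5.45-fold lower, from 7911 to 1453, with log2 ratios from -2.82 to -2.45 across 3 probe sets. LYPD1 was 4.99-fold lower, KLHL6 4.65-fold lower in its brightest probe set (at least 2.14-fold and 1.41-fold in others), and TMPRSS4, a membrane serine protease, 4.08-fold lower. PMEPA1, an inhibitor of SMAD signalling, was 2.70-fold lower in its brightest probe set and was lower in all 3. CEL, PUS10, ACSM3 and ZC3H6 were 2.71, 3.24, 3.24 and 2.97-fold lower, with weaker ratios in another probe set of ACSM3 (-0.98) and of ZC3H6 (a bound of -0.82). The lists fixed in advance held 70 of the 180 higher genes and 7 of the 187 lower genes, RUNX2 among these 7. The share of all measured genes that stand in a list was not counted. The smaller number among the lower genes is therefore not read as a depletion.

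Among genes with 2 or more measured probe sets, all probe sets were at least 1.5-fold higher for 49 of 97 higher genes and at least 1.5-fold lower for 35 of 81 lower genes. Another probe set went at least 1.5-fold the other way in 0 of the higher and 3 of the lower genes. With the floor at the 75th percentile the counts were 112 and 79, and with an offset in place of the floor they were 114 and 91.

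**Figure D2:**
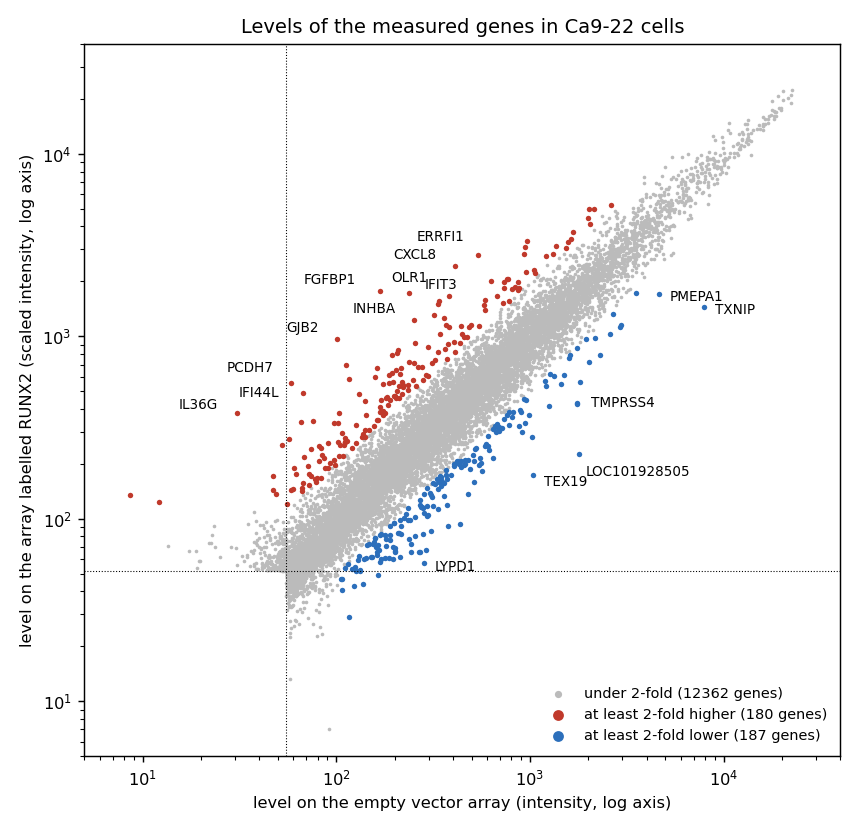
Level of each of the 12729 measured genes on the empty vector array (horizontal, intensity) and on the array labelled RUNX2 (vertical, scaled intensity), both on log axes, with dotted lines at the floors. The 180 genes at least 2-fold higher are red, the 187 at least 2-fold lower are blue, and FGFBP1 and TXNIP lie far from the diagonal on either side.

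Interferon-stimulated genes formed the list with the highest median. Of 29 measured members, 21 were at least 2-fold higher and 0 at least 2-fold lower in the array labelled RUNX2, with a median log2 ratio of 1.38, above all 10000 random lists (percentile 100). EPSTI1 was 5.17-fold higher in its brightest probe set and at least 2.13-fold in another, the antiviral RNA-binding proteins IFIT3 and IFIT1 were 4.61-fold and 4.10-fold higher, OAS1, which senses double-stranded RNA, was 3.79-fold higher, and the ubiquitin-like modifier ISG15 went from 942 to 3069. The cytosolic RNA sensor RIGI was 5.03-fold higher in its brightest probe set and 4.91-fold in another, while a further one had a log2 ratio of -0.07. IRF1, with -0.16, was the member below 0. The list of MHC and antigen presentation genes did not share this shift. None of its 19 measured members differed by 2-fold and the median log2 ratio was -0.00 (percentile 75.7). NLRC5 had 0.76, TAP1 0.41 and HLA-E -0.46, with -1.05 in another probe set of HLA-E. Leukocyte markers, given here because immune cells express many interferon-stimulated genes, had a median log2 ratio of 0.08 over 9 measured members (percentile 98.1), with 0 at least 2-fold higher, CORO1A highest at a bound of at least 0.48 (55.2 on the empty vector array, just under the floor, and 77.2) and LCP1 next at 0.47, and under 6 of the alternatives tried the list lay within the limits.

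Genes of the G1/S transition and DNA replication were higher as a list, and mitotic genes were not. The median log2 ratio of 30 measured G1/S and replication genes was 0.71 (percentile 100). Of these, 6 were at least 2-fold higher, 0 were at least 2-fold lower, and 29 lay above 0. CCNE2, a cyclin of the G1/S transition, was 3.69-fold higher in its brightest probe set and at least 1.36-fold in another, and the replication initiation factor CDC6 was 2.31-fold higher. MCM10, another initiation factor, was 2.48-fold higher in its brightest probe set but 1.33-fold and 1.19-fold in the others, and RRM2, a subunit of ribonucleotide reductase, was 2.35-fold higher in its brightest probe set, from 952 to 2239, and 1.69-fold in the other. The 31 measured mitosis genes had a median of -0.10 (percentile 15.5) with 0 passing 2-fold either way. HMMR had a log2 ratio of -0.53, and NEK2 and TOP2A of -0.51. The list of p53 targets and cell cycle inhibitors had a median of 0.12 over 20 genes (percentile 95.2), with 2 at least 2-fold higher and 1 at least 2-fold lower, and it passed the upper limit under 3 alternatives. TP53I3 was 2.91-fold higher, PMAIP1, which encodes the pro-apoptotic protein NOXA, was 2.47-fold higher, and the cyclin-dependent kinase inhibitor CDKN2B was 2.35-fold lower.

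Immediate early genes, which respond to growth factor signalling, had a median log2 ratio of 0.42 over 23 measured members (percentile 100), with 9 at least 2-fold higher and 0 at least 2-fold lower. DUSP6, a phosphatase that switches off ERK, was 4.06-fold higher and had log2 ratios of 1.76 to 2.03 over 3 probe sets. PHLDA1 was 3.20-fold higher in its brightest probe set and between 1.49-fold and 6.09-fold over 6, and the transcription factor FOSB was 3.17-fold higher. ATF3 was 2.96-fold higher in its brightest probe set and 1.12-fold in the other that was above the floor on both arrays. Cytokines, chemokines and NF-kB response genes had a median of 0.42 over 23 genes (percentile 100), with 6 at least 2-fold higher and 0 lower. Besides IL36G and CXCL8, TNFAIP3, a feedback inhibitor of NF-kB, was 3.59-fold higher and the chemokine CXCL2 was 3.48-fold higher, whereas IL1B had a log2 ratio of -0.89. Angiogenic and growth factors had a median of 0.12 over 23 genes (percentile 99.1), with 6 at least 2-fold higher and 0 lower. FGFBP1 headed this list. The lymphatic growth factor VEGFC was 3.21-fold higher, the EGF receptor ligands HBEGF and TGFA were 3.11-fold and 2.28-fold higher, with the other probe sets of TGFA below the floor on the empty vector array. VEGFA, named in advance, had 0.12 in its brightest probe set and up to 0.58 in others. With an offset in place of the floor this list lay within the limits, at percentile 96.9.

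Keratinocyte genes were higher in part. Basal keratinocyte genes had a median log2 ratio of 0.29 over 16 genes (percentile 99.9), with 2 at least 2-fold higher and 1 at least 2-fold lower. The basal keratin KRT14 was 2.69-fold higher, and the hemidesmosome integrin ITGB4 was 2.55-fold higher in its brightest probe set. ITGB4 was also 2.10-fold and 1.74-fold higher in other probe sets. It had a log2 ratio of -0.11 in a further one near the floor on both arrays (56.5 and 52.5). Its partner ITGA6 had 0.95, and the stem cell factor SOX2 was 2.64-fold lower, with a log2 ratio of -0.90 in another probe set. The basal list lay within the limits, at percentile 93.6, when ratios were averaged over probe sets. Differentiation and cornification genes had a median of 0.22 over 25 genes (percentile 99.97), with 4 at least 2-fold higher and 0 lower. S100A8, a calcium-binding alarmin, was 4.78-fold higher, from 57.2 to 273. KLF4, a transcription factor of barrier formation, was 2.66-fold higher, the protease inhibitor SLPI 2.25-fold and the cornified envelope protein SPRR1B 2.18-fold.

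Junction genes and mesenchymal genes stayed within the limits of random lists. Among 30 epithelial junction and identity genes the median was -0.04 (percentile 35.7), with 2 at least 2-fold higher and 0 lower. The tight junction gene CLDN1 was 6.19-fold higher in its brightest probe set, while its other measured probe set was below the floor on the empty vector array and gave a bound of 0.08 on the log2 scale, and OVOL1, a repressor of mesenchymal genes, was 2.54-fold higher. EPCAM had -0.89 and E-cadherin, CDH1, had 0.01, with levels of 3545 and 3580. Among 18 mesenchymal and EMT genes the median was 0.05 (percentile 89.6), with 2 at least 2-fold higher and 0 lower. The matricellular genes CCN2 and THBS1 were 3.14-fold and 2.07-fold higher, SNAI2 had a log2 ratio of 0.86, and VIM, vimentin, was at least 1.78-fold lower against the floor. With the floor at the 75th percentile the EMT list passed the upper limit. Integrin and matrix genes had a median of -0.09 over 31 genes (percentile 27.6), with 3 at least 2-fold higher, ITGB4, THBS1 and the collagen COL12A1 (2.24-fold), and 0 lower.

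Activin, TGF-beta and BMP signalling genes went both ways. The median of 30 measured genes was 0.10 (percentile 97.1), with 3 at least 2-fold higher and 2 at least 2-fold lower. Beside INHBA, ID2, an inhibitor of helix-loop-helix factors and a BMP target, was 3.93-fold higher and BMP2 was 2.13-fold higher, while the signal transducer SMAD3 was 2.45-fold lower and the activin receptor ACVR2B 2.16-fold lower in their brightest probe sets. In the other probe sets above the floor on both arrays, log2 ratios were -0.70 and -0.45 for SMAD3 and -0.63 and -0.28 for ACVR2B. This list passed the upper limit under 4 alternatives.

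Osteoblast genes and textbook RUNX2 targets had a median of 0.01 over 12 measured of 27 genes with a probe set (percentile 69.4), and BMP2 was the 1 member at least 2-fold higher. MSX2 had a log2 ratio of 0.76, and 0.24 in its other measured probe set. MMP13, a collagenase regulated by RUNX2 in bone, had 0.13, at levels of 4659 and 5114. SPP1, osteopontin, and MMP9 lay below the floor on both arrays. Matrix proteases, the plasminogen system and their inhibitors had a median of -0.17 over 26 genes (percentile 4.75), with 0 at least 2-fold higher. Tissue plasminogen activator, PLAT, was 2.28-fold lower, PLAUR had a log2 ratio of 0.95 and SERPINB5 one of 0.92. Wnt and Notch genes had a median of -0.18 over 28 genes (percentile 5.48). The Wnt inhibitor DKK1 was 2.01-fold higher, and the receptor FZD2 was 2.16-fold lower in its brightest probe set and 1.16-fold in the other. NOTCH3 had -0.98, and -0.15 in its other probe set. After quantile normalization this list stood at percentile 1.79, below the lower limit.

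Hypoxia and glycolysis genes had a median log2 ratio of 0.35 over 28 genes (percentile 100), with 3 at least 2-fold higher and 0 lower. EGLN3, a prolyl hydroxylase induced by HIF, was 3.26-fold higher, ANKRD37 was 3.05-fold higher, adrenomedullin, ADM, went from 2632 to 5267, and hexokinase HK2 had 0.99. Heat shock and chaperone genes had a median of 0.24 over 16 genes (percentile 99.7), with HSPH1 2.06-fold higher and DNAJA1 at 0.94. Oxidative stress and NRF2 genes had a median of 0.13 over 22 genes (percentile 97.9), with 0 passing 2-fold. GCLM had 0.99 and NQO1 0.75, and 3 alternatives put this list within the limits. Unfolded protein and amino acid response genes (median 0.06, 25 genes, percentile 83.5) and cholesterol and fatty acid synthesis genes (median 0.02, 19 genes, percentile 63.7) had 0 members passing 2-fold. CHAC1 had a log2 ratio of 0.73, DNAJB9 of -0.75 and FDPS of 0.48. Cytosolic ribosomal protein genes were the list that lay below the lower limit, with a median of -0.16 over 33 genes (percentile 0.36), 32 of them below 0 and RPL14 lowest at -0.40. That call was lost after quantile normalization (percentile 3.72), without probe sets that can match several transcripts (11.3) and against random lists not matched on level (8.68). Oxidative phosphorylation genes had a median of 0.00 over 29 genes (percentile 55.8), from SDHD at -0.46 to NDUFB8 at 0.35. Other probe sets of NDUFB8 had 0.28 and -0.23.

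Common reference genes had a median of 0.12 over 13 genes (percentile 92.7). The transferrin receptor TFRC was 2.33-fold higher in its brightest probe set and 2.51-fold in another. A further probe set near the floor on both arrays (59.8 and 53.2) had a log2 ratio of -0.17. PGK1 had 0.83 and GUSB -0.51. Markers of other cell types showed no 2-fold difference. The 9 measured markers of simple and glandular epithelium had a median of -0.05 (percentile 64.9), with KRT19 at 0.33 and MUC16 at -0.49. Of the fibroblast markers 3 were measured (COL1A1 -0.32, FBLN1 -0.31, and THY1 with a bound of -0.45 against the floor) and of the endothelial markers 4 (FLT1 0.45, PECAM1 -0.32, VWF -0.44, ENG -0.48), too few to rank. FLT1 and PECAM1 each rest on 1 probe set, and their other probe sets lay below the floor on both arrays. Of 28 ranked lists, 11 lay above the limits, 1 below and 16 within. Random lists hold genes drawn independently, whereas genes of 1 pathway vary together, so these counts are not set against a number expected by chance.

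**Figure D3:**
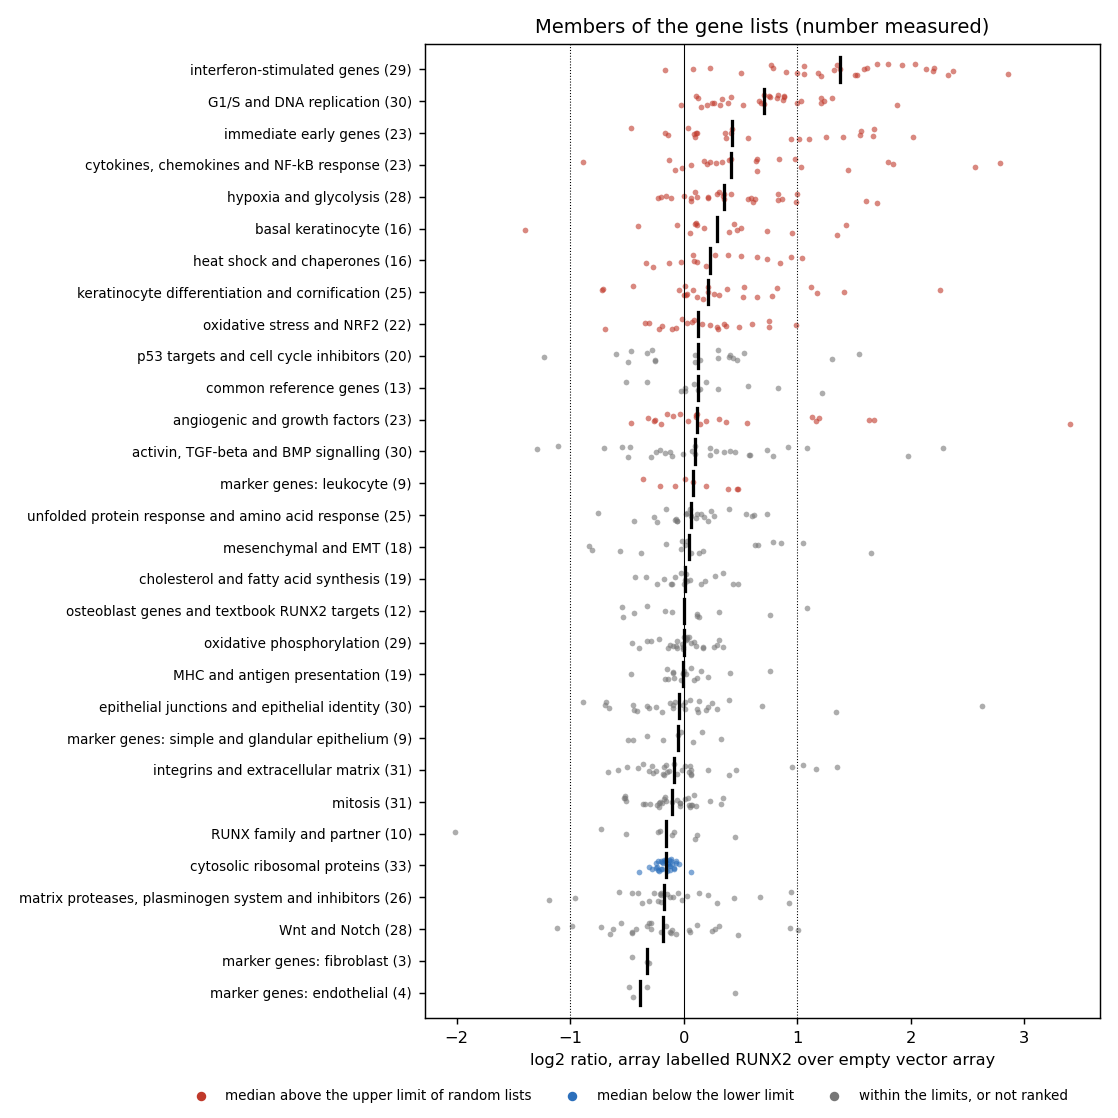
Log2 ratio of every measured member of the 30 gene lists (points, spread vertically at random within a list), with a black bar at each median, a solid line at 0, dotted lines at 2-fold, and the number of measured members beside each name. The interferon list sits farthest to the right, with a median of 1.38, followed by the G1/S and replication list at 0.71, and the ribosomal protein list is narrow around -0.16.

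The 3' to 5' signal ratio of the ACTB control probe sets, a measure of RNA integrity and labelling length, was 2.90 on the empty vector array and 2.28 on the array labelled RUNX2, and that of GAPDH was 1.10 and 1.07. The 18 hybridisation spike-in probe sets, added at equal amounts in the usual Affymetrix procedure, had a median log2 ratio of 0.19, between -0.08 and 0.40.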

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

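The counts of this part were chosen after the main result was seen. Among 5278 measured probe sets that carry no single gene name, and so entered no comparison, 82 were at least 2-fold higher and 94 at least 2-fold lower in the array labelled RUNX2. These are 1.55% and 1.78% of them, against 1.41% and 1.47% of the named genes, and their log2 ratios ran from -3.22 to 3.36. Among the control probe sets, which were left out of the gene counts, 3 were at least 2-fold higher and 0 at least 2-fold lower. They stand here as signals outside the main measurement, without an explanation.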

How the results depend on the processing

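The values per RUNX2 probe set and the interferon and G1/S lists with members left out were chosen after seeing the data. The interferon alternative removed no measured member, so it tested nothing. With 1 array per group, leaving out a replicate was not possible. Of the gene list values under alternatives, 301 kept their call or, if unranked, their value, 14 lost a call, 9 gained one and 2 of unranked lists moved. Of the values of named genes other than RUNX2, 1267 moved by less than the spread between probe sets and 85 moved by more. Some small ratios changed sign. Without _x_at and _s_at probe sets, RPL14 went from -0.40 to 0.03 and FBLN1 from -0.31 to 0.09. No paired analysis was possible because each group held 1 array. No scaling moved the median of all genes by over 0.1. The main counts, 180 higher and 187 lower, became 112 and 79 with the floor at the 75th percentile, 114 and 91 with an offset in place of the floor, 734 and 873 at 1.5-fold and 22 and 11 at 4-fold, as fewer or more genes can pass by construction. On the deposited scale they were 209 and 156, or 57.3% higher against 49.0% in the chosen scaling. The RUNX2 log2 ratio reversed to 0.62 with the mean over probe sets, since these disagree, and 221282_x_at gave 0.84 with the floor at the 75th percentile and 1.37 with the offset, which raise its low value. For the lists below, median log2 ratios are given and the cause was not tested. After quantile normalization p53 targets (0.16) passed above the upper limit, Wnt and Notch (-0.20) below the lower one, and ribosomal proteins (-0.10) came within. With the floor at the 25th percentile and with no floor, activin and TGF-beta passed above (0.10 in both) and leukocyte markers came within with the sign turned (-0.21 in both). With the floor at the 75th percentile EMT passed above (0.20), NRF2 came within (0.093) and the endothelial markers moved to 0.45. With the offset, activin and TGF-beta passed above (0.11), and growth factors (0.046) and leukocyte markers (0.0050) came within. With the mean over probe sets p53 targets passed above (0.31), and basal keratinocyte genes (0.13), NRF2 (0.11) and leukocyte markers (0.0079) came within. Without _x_at and _s_at probe sets NRF2 (0.14), ribosomal proteins (-0.15) and leukocyte markers (0.0079) came within, and the fibroblast markers moved to 0.092. Against random lists not matched on level, activin and TGF-beta (0.10) and p53 targets (0.12) passed above, and ribosomal proteins (-0.16) and leukocyte markers (0.085) came within. Signal over background limits genes near the floor, whose ratios are bounds.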

Other observations

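The gene families of this paragraph and the next, and all tests below except those of scaling and of level bias, were chosen after the results were seen. Connexins, the subunits of gap junctions, had 2 of 7 measured members at least 2-fold higher in the array labelled RUNX2, GJB2 (9.56-fold) and GJB5 (2.60-fold), and GJA1 had a log2 ratio of 0.57. Genes that damp ERK signalling or report it had 4 of 10 measured members at least 2-fold higher, DUSP6 at 2.02, SPRED2 at 1.67, DUSP5 at 1.40 and SPRED1 at 1.23, while SPRY2 had 0.04 and SPRY4 -0.14. SPRY1 was lower against the floor, with a bound of -0.48. Of 6 measured genes for EGF receptor ligands and the receptor's inhibitor ERRFI1, 4 were at least 2-fold higher, ERRFI1, HBEGF, TGFA and EREG (2.18-fold). TXNIP and its relative ARRDC4, both known to respond to glucose through the same transcription factors, were 5.45-fold and 3.61-fold lower, while ARRDC3 had a log2 ratio of 0.39.

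Claudins had 1 of 12 measured members at least 2-fold higher, CLDN1, and CLDN4 had a log2 ratio of -0.69. Keratins had 1 of 16 at least 2-fold higher, KRT14, with KRT5 at 0.51 and KRT13, a keratin of the oral mucosa, at -0.72. Of 15 measured genes with symbols starting in S100, including S100PBP, which is no S100 protein itself, 1 was at least 2-fold higher. This was S100A8, while its partner S100A9 had 0.00. The G1/S list without its 2-fold higher members had a median of 0.59.

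The higher interferon-stimulated genes in the array labelled RUNX2 were weighed against technical sources. A scaling or level-dependent bias is argued against, since the list median was at least 1.42 after quantile normalization and after loess. Leukocytes mixed into the culture are not excluded by the markers, though the cells were a carcinoma line selected with blasticidin after transduction. Of 17 marker genes with a probe set 9 were measured, and the list stood at percentile 98.1. The highest log2 ratio was 0.48, a bound for CORO1A, but only 1 marker, LCP1, lay above 2 floors, and its level of 775 on the empty vector array would hide a small share. A response to vector delivery or to culture state rather than to RUNX2 cannot be told apart from an effect of RUNX2, since there was 1 array per group.

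The RUNX2 probe sets going opposite ways leave open what the arrays hold. An exchange of the arrays cannot be told apart from correct labels, because 216994_s_at had a log2 ratio of 2.06 and 221282_x_at was higher too, while 232231_at goes the other way. A transferred copy without the part that 232231_at reads, with less of the cell's own transcript, may give the -2.01 of that probe set, but this cannot be told apart from the exchange without the vector and probe sequences, which were not used here.

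Long non-coding RNAs were more frequent among the lower genes than among the higher ones. Of 747 measured, 41 were at least 2-fold lower and 4 at least 2-fold higher, with a median log2 ratio of -0.25, against 139 lower and 173 higher of 11734 protein-coding genes with a median of -0.05. LOC101928505, LINC00173, ZNF436-AS1 and MRNIP-DT were among the lowest. A level-dependent bias is argued against, since the median stood at percentile 0 of level-matched random lists in the chosen scaling and after loess, and so is the later array design, within which long non-coding and protein-coding probe sets still differed in their medians by -0.17. RNA integrity or labelling length may contribute and cannot be told apart from biology, since the ACTB 3' to 5' ratio of the array labelled RUNX2 was 0.787 of that of the empty vector array.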
